A study of Homo sapiens with 6 samples.

How the data were processed

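RNA was measured by sequencing of rRNA-depleted total RNA from human CD34+ hematopoietic stem and progenitor cells. There were 6 libraries in 3 groups of 2: DMSO (the solvent control), DAC (decitabine) and UNC (UNC0638). Libraries are named here by group and replicate number.

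Per the labels, the authors extracted total RNA with Trizol, treated it with DNase and prepared libraries with a kit that removes ribosomal RNA. Their notes name FastQC 0.11.8, Trim Galore 0.4.5, TopHat2 2.1.1, Bowtie, HTSeq 0.6.1 and DESeq2, and the genome build hg19. The role of each tool, the annotation, the strand setting and the handling of reads with several positions are not given in the sources used here. The deposited values are raw counts, 1 value for each of 66340 RefSeq transcript entries in every library. Isoforms of a gene share reads: among 8416 genes with several entries and a top mean count of at least 100, the lowest entry lay within 10% of the top entry in 52.5%. Library totals over transcript entries therefore exceed the number of reads. MALAT1 and TALAM1, which overlap on opposite strands, had near-equal counts (TALAM1 to MALAT1 ratio 0.99 to 0.993 over the libraries). Reads therefore appear to have been counted without regard to strand, and genes that overlap an antisense RNA may carry its reads. Genes had been assumed to be the unit when the tests were planned. The deposited tables hold no tally of reads outside genes, so a planned share of such reads could not be computed.

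Entries were named through the RefSeq table (65289) or the GENCODE annotation (526), and 525 had no gene name. Genes of the Y chromosome, XIST and TSIX were left out (366 entries). For each gene the transcript with the highest mean count over the 6 libraries was kept, which gave 27510 genes. The reference annotation is on GRCh38 and the reads were aligned to hg19, so chromosomes are given and positions are not. No mitochondrially encoded gene was among the entries.

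Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a lowest count of 10 and a lowest total of 15, and a quasi-likelihood F test (two-sided) in 1 fit of all 6 libraries with group as the only term and 3 residual degrees of freedom. The filter left 18452 genes. It can keep a gene counted in 1 group alone, and shares of a list are over its tested members. Adjusted p-values are Benjamini-Hochberg, and a gene passed at an adjusted p under 0.05. Fold changes used a prior count of 0.125. CPM values are edgeR's, from gene counts and TMM-scaled library sizes, given as mean ± SD with n = 2 libraries per group. Contrasts were decitabine against DMSO, UNC0638 against DMSO and UNC0638 against decitabine.

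Of 36 gene lists written for these cells and treatments, 35 had at least 5 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of each contrast. The lists hold cell type markers (immature CD34+ cells, erythroid, megakaryocyte, neutrophil granule, monocyte, dendritic, mast cell with basophil and eosinophil, B lymphoid, T and NK, endothelial and stromal), pathways (globins, MHC class I, MHC class II, interferon, NF-kB and inflammation, p53, S phase, mitosis, sterol synthesis, lysosome, integrated stress response, H3K9 methylation machinery, DNA methylation machinery, nucleoside drug metabolism), classes of silenced genes (cancer-testis and germline, imprinted) and families (ZNF zinc fingers, HOX clusters, clustered protocadherins, keratins, olfactory receptors, replication histones, ribosomal proteins). Immediate early genes and abundant non-coding RNA were included as signs of handling and RNA quality. Camera was repeated with an estimated correlation, and fry was run as a test of each list by itself. Called genes were compared with protein-coding genes by annotated class with Fisher's exact test, two-sided. That test takes genes as independent units, which they are not, and its p-values do not measure the spread between libraries.

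The genes named in the text follow a rule: the 10 largest rises and 10 largest falls against DMSO (5 and 5 for UNC0638 against decitabine) with a mean of at least 1 CPM and both treated libraries beyond both control libraries, the 4 members of each list with the smallest adjusted p, and EHMT1, EHMT2, DNMT1, DNMT3A, DNMT3B, UHRF1, CD34, HBG1 and HBG2. The groups, contrasts, tests, gene lists, this rule and most alternatives were fixed before the data were examined. MPO, HBB, BCL11A, GATA2 and CEBPE, and for UNC0638 against decitabine PRG2, BPI, HBG2, HBE1, CD34, HLA-DRA and ZNF274, were chosen after their values were seen. So were list members named because they moved against their list: KIT, CSF3R, LYZ and HBD with decitabine, and ALOX15, CMA1, PRG3, CTSG, LCN2, LTF, RNASE3, APOE, PDGFA, FLT3, HOPX, SPINK2, KIT, CLEC9A and HBZ with UNC0638. Some genes that the rule selects, and 1 alternative fit, are not reported here.

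Alternatives were DESeq2 1.42.0 size factors and Wald test, upper quartile factors, limma-voom, other filters, stricter thresholds, only the groups compared, a replicate term and leaving out each library. Library size without factors, counts summed over transcripts, every transcript entry by itself, 1 DMSO library for each contrast (2 residual degrees of freedom, for shared calls), and a fit without genes that match an overlapping neighbour were added after the data were seen. The pipeline was tested on simulated data: with 18076 genes and 50 planted changes at each size, it called 42% at 1.25-fold, 68% at 1.5-fold, 60% at 2-fold and 98% at 4-fold, and 9 genes with no planted change. Camera called the planted list and 0 of 30 others. Genes were simulated independently and the lists were random genes. This does not test camera on lists with correlated members, such as ribosomal proteins (estimated correlation 0.48 with decitabine).

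Library totals were 170592515 to 207760694 counts over transcript entries and 62306071 to 76386697 over genes. Counting intervals are 95% and exact (Clopper-Pearson), and a group with no count was set at 3 counts over the group. Intervals and floors cover counting error only. With 2 libraries against 2, a permutation of 1 value cannot give a p below 0.333. The share of HBG2 was compared by t tests with the variance pooled over the 6 libraries (two-sided, 3 residual degrees of freedom, adjusted over the 3 contrasts), chosen after the data were seen. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.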

Results

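RNA was measured in human CD34+ hematopoietic stem and progenitor cells, the immature cells from which all blood lineages form. Of 3 groups of 2 libraries, DMSO was the solvent control. The DAC group received decitabine, a cytidine analogue that is built into DNA and traps DNA methyltransferases. The UNC group received UNC0638, an inhibitor of the histone methyltransferases G9a (EHMT2) and GLP (EHMT1), which place the H3K9me2 mark. Doses, treatment times and culture conditions are not given in the sources used here. In bulk RNA, a shift in which cells were present cannot be told apart from a change within cells, for any list below. Gene counts were 76196659 and 76386697 in DMSO replicates 1 and 2, 71100767 and 75825293 in DAC replicates 1 and 2, and 62306071 and 66130445 in UNC replicates 1 and 2. Nothing in the labels says that the libraries of a group came from separate cultures or donors, so p-values measure the spread between these libraries, which may be technical. That spread was 4.87% as a biological coefficient of variation, and replicates correlated across genes at Pearson r = 0.991 in DMSO, 0.993 in DAC and 0.99 in UNC, where genes are not independent replicates. The first principal component (58.3% of variance) separated both DAC libraries from the others, and the second (24.8%) separated DMSO from UNC.

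The first comparison asked which transcripts differed after inhibition of DNA methylation. With decitabine, genes of granulocyte granules rose far above DMSO. PRG2, the major basic protein of eosinophil granules, went from 1771 ± 60.8 to 7653 ± 83.6 CPM (SD, n = 2). EPX, the eosinophil peroxidase, went from 982 ± 24.8 to 3612 ± 38.0 CPM, CLC, which forms Charcot-Leyden crystals, from 972 ± 35.9 to 3017 ± 31.1 CPM, and HDC, the histamine-forming enzyme, from 367 ± 12.3 to 1271 ± 5.89 CPM. Of 25 mast cell, basophil and eosinophil genes, 24 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 fold change of 1.79. KIT, the receptor for stem cell factor, was the member that fell (-0.52 log2). Camera gave this list an adjusted p of 3.92e-68, and an adjusted p = 0.00996 with an estimated correlation. CEBPE and GATA2, transcription factors of granulocyte and of mast cell and early blood development, also rose, from 5.94 ± 0.495 to 32.3 ± 0.0566 CPM and from 238 ± 1.29 to 780.5 ± 24.3 CPM.

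Neutrophil granule genes rose with decitabine as well. BPI, a bactericidal protein, went from 11.1 ± 0.767 to 149 ± 0.592 CPM (SD, n = 2), CTSG, cathepsin G, from 118 ± 1.52 to 619 ± 3.34 CPM, and MS4A3, a marker of granulocyte-monocyte progenitors, from 35.0 ± 2.92 to 284 ± 6.14 CPM. CEACAM6, an adhesion protein gene, rose by 3.40 log2. The neutrophil defensin genes DEFA1, DEFA1B and DEFA3, near-identical copies whose reads cannot be assigned with certainty, rose by 5.99, 5.99 and 5.84 log2. Of 30 neutrophil granule genes, 25 rose and 3 fell, the same counts adjusted over the list alone (median 2.12 log2, camera adjusted p = 1.77e-42, and adjusted p = 0.0253 with an estimated correlation). The members that fell were MPO, the myeloperoxidase of early granules (-1.03 log2, 7119 ± 13.9 to 3490 ± 32.8 CPM), LYZ, lysozyme (-0.44), and CSF3R, the G-CSF receptor (-0.30).

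Genes of MHC class II, the complex that presents antigens to helper T cells, fell with decitabine. HLA-DRA, a chain of the class II dimer, went from 501 ± 24.6 to 126 ± 2.73 CPM (SD, n = 2), and CIITA, the master regulator of class II genes, from 78.5 ± 1.13 to 18.0 ± 1.62 CPM. CD74, the invariant chain, fell by 1.78 log2. None of 16 class II genes rose and 13 fell, the same adjusted over the list alone (median -1.78 log2, camera adjusted p = 9.59e-40, and adjusted p = 0.0233 with an estimated correlation). MHC class I moved the other way: HLA-B rose by 0.72 and NLRC5, an activator of class I genes, by 1.15 log2. Of 16 class I genes, 9 rose and 5 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.000315, but adjusted p = 0.144 with an estimated correlation).

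Markers of lymphoid, monocytic and immature cells changed too. DNTT, the terminal transferase of early lymphoid cells, went from 21.9 ± 4.38 to 0.115 ± 0.0431 CPM (SD, n = 2), the largest fall among the genes named by rule. BLNK, a B cell adaptor, fell by 4.45 log2 and MME, the CD10 antigen of lymphoid progenitors, by 2.77. Of 17 B lymphoid genes, 1 rose (CD24) and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.00521, adjusted p = 0.269 with an estimated correlation). Monocyte and macrophage genes split, with 13 of 31 higher and 11 lower, also adjusted over the list alone (camera adjusted p = 0.319). The integrin gene ITGAM rose by 2.39 log2, while the M-CSF receptor gene CSF1R fell by 2.66, the mannose receptor gene MRC1 by 2.54 and the transcription factor gene IRF8 by 2.81. That list had a median of 0.20 and a mean of -0.04 log2. Dendritic cell genes split likewise, 5 of 17 higher and 9 lower by either adjustment (camera adjusted p = 0.96), with CLEC10A at -2.10 and the high-affinity IgE receptor gene FCER1A at 1.96 log2. Among genes of immature cells, CD34 went from 73.3 ± 1.01 to 34.7 ± 2.45 CPM, and the receptor genes FLT3 and PROM1 fell by 3.01 and 2.12 log2. Of 31 such genes, 5 rose and 12 fell by either adjustment. Their median was 0 and their mean -0.19 log2 (camera lower, adjusted p = 0.00109, adjusted p = 0.167 with an estimated correlation).

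Red cell genes rose with decitabine, embryonic and fetal globins among them. HBE1, embryonic epsilon globin, went from 1.47 ± 0.238 to 55.4 ± 0.426 CPM (SD, n = 2). HBG2 and HBG1, the near-identical fetal gamma globins, went from 81.0 ± 12.7 to 269 ± 12.2 CPM and from 55.1 ± 14.3 to 194 ± 5.87 CPM. HBB, adult beta globin, fell by 0.43 log2 and HBD, delta globin, by 0.57. BCL11A, a repressor of the fetal globin genes, fell from 47.2 ± 0.943 to 21.8 ± 1.49 CPM. HBG2 made up 26.1% ± 2.33 of HBG2 plus HBB counts in DMSO and 61.5% ± 2.19 in decitabine (SD, n = 2, t test with pooled variance, Benjamini-Hochberg adjusted p = 0.000479). Of 10 globin genes, 7 rose and 2 fell by either adjustment (camera adjusted p = 1.28e-07, adjusted p = 0.133 with an estimated correlation). Of 33 erythroid genes, 25 rose and 2 fell, the same adjusted over the list alone, with carbonic anhydrase CA1 at 4.29 and the band 3 gene SLC4A1 at 2.74 log2 (camera adjusted p = 2.21e-10, adjusted p = 0.133 with an estimated correlation). In the megakaryocyte list, 9 of 22 genes rose and 3 fell, also adjusted over the list alone, with ITGA2B, platelet integrin alpha IIb, at 0.96 log2. Its camera adjusted p of 0.0385 became 0.109 without DMSO replicate 2 and 0.142 without DAC replicate 2, and the adjusted p = 0.599 with an estimated correlation.

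**Figure D1:**
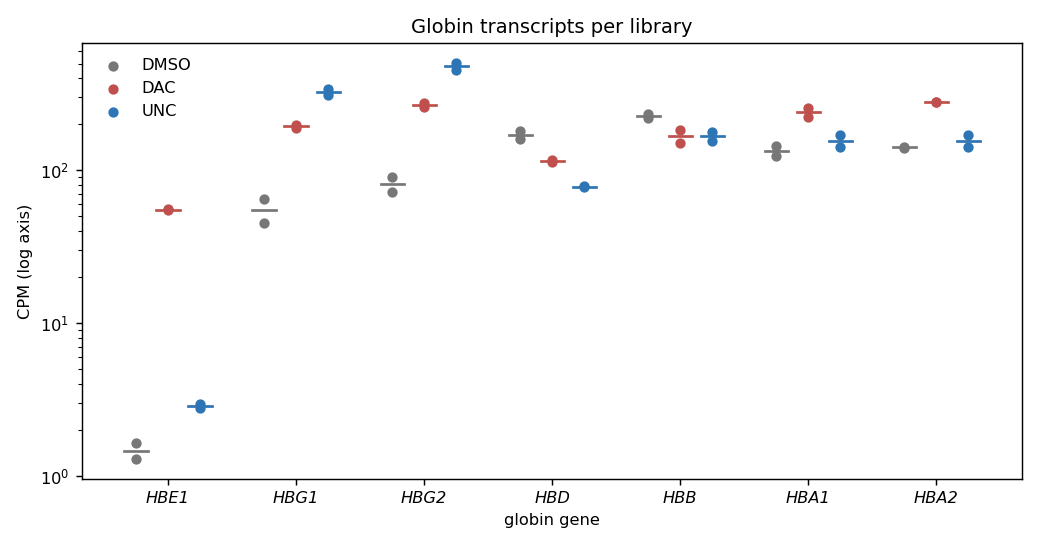
Normalised abundance (CPM, log axis) of globin genes in each library, with the group mean as a line. HBG2 rose from 81.0 CPM in DMSO to 269 in decitabine and 479.6 in UNC0638, while HBE1 reached 55.4 CPM in decitabine and 2.88 in UNC0638.

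Targets of p53, a transcription factor of the damage response, rose with decitabine. CDKN1A, the p21 cell cycle inhibitor, went from 29.6 ± 0.486 to 95.8 ± 4.56 CPM (SD, n = 2), and of 39 p53 targets 27 rose and 4 fell (28 and 4 adjusted over the list alone, camera adjusted p = 9.99e-07, adjusted p = 0.269 with an estimated correlation). Of 34 inflammatory genes 24 rose, CCL5 by 1.76 and TNFAIP3, a feedback inhibitor of NF-kB, by 1.60 log2, and 3 fell (25 and 3 adjusted over the list alone, camera adjusted p = 5.6e-08, adjusted p = 0.269 with an estimated correlation). Immediate early genes, which also respond to handling, rose in 13 of 23 cases and fell in 4 by either adjustment (camera adjusted p = 0.00663, adjusted p = 0.437 with an estimated correlation). Among interferon response genes 9 of 42 rose and 20 fell (10 and 22 adjusted over the list alone), with the antiviral sensors OAS2 at -2.81 and OAS1 at -2.49 log2. The camera adjusted p of 0.0303 for that list became 0.0589 under a filter of 1 CPM, and the adjusted p = 0.303 with an estimated correlation.

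Ribosomal protein genes fell by a median of 0.51 log2, 76 of 78 lower and 1 higher by either adjustment, with RPL5 at -0.69 (camera adjusted p = 1.02e-26, adjusted p = 0.269 with an estimated correlation). MYC, a transcription factor, fell by 1.10 log2. S phase genes fell in 31 of 44 cases and rose in 1 (32 and 1 adjusted over the list alone), with the replicative helicase genes MCM4 and MCM6 at -0.42 and -0.48 log2 (camera adjusted p = 0.000963, adjusted p = 0.437 with an estimated correlation). Replication histones fell in 53 of 66 cases and rose in 5 by either adjustment, where the testis variant H1-6 rose by 4.08 log2 (camera adjusted p = 1.07e-05, adjusted p = 0.437 with an estimated correlation). Mitosis genes fell in 22 of 37 cases and rose in 3 by either adjustment. The camera adjusted p of 0.0303 for mitosis became 0.0963 under a filter of 1 CPM, and the adjusted p = 0.454 with an estimated correlation.

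Genes nearly silent in DMSO appeared with decitabine. APOC2, an apolipoprotein that shares reads with the APOC4-APOC2 readthrough, went from 0.222 ± 0.0843 to 68.9 ± 3.74 CPM (SD, n = 2), the largest rise among the genes named by rule. COL14A1, a fibril-associated collagen, went from 0.478 ± 0.0697 to 53.2 ± 0.147 CPM, and CYP11A1, which starts steroid synthesis, from 0.148 ± 0.0181 to 15.5 ± 1.09 CPM. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, the adjusted p was 8.24e-16 for APOC2, 1.01e-15 for COL14A1 and 2.4e-13 for CYP11A1. Both DAC libraries lay above both DMSO libraries for each, which the rule for the largest rises requires. In all, 45 genes had at least 10 counts in each DAC library and 0 in both DMSO libraries, against 5 genes the other way round. The filter left 15 of 57 keratin genes and 22 of 53 clustered protocadherin genes with an entry. Keratins, structural proteins of epithelia, rose in 9 of 15 tested members and fell in 1 by either adjustment, with KRT81 at 3.86 log2. KRT17 had 93 counts against 1 in DMSO, a ratio of 96.6 with a 95% counting interval of 16.9 to 3860 (keratin list, camera adjusted p = 0.0011, adjusted p = 0.228 with an estimated correlation). The 22 tested protocadherins were all of the gamma cluster, and all rose by either adjustment (PCDHGA11 1.05 log2). A median of 92.8% of a member's count was also carried by every other member, so they are not separate measurements (camera adjusted p = 0.00189, adjusted p = 0.583 with an estimated correlation).

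Other lists often linked to DNA methylation were mixed. The filter left 20 of 55 cancer-testis and germline, 16 of 39 HOX and 34 of 388 olfactory receptor genes with an entry. It can keep a gene counted in 1 group alone, so shares of tested members are not shares of a family. Cancer-testis and germline genes rose in 7 of 20 tested members and fell in 2 by either adjustment (camera adjusted p = 0.158). TDRD9, a germline RNA helicase, rose by 1.02 log2, and MAGEB2 had 42 counts against 2 in DMSO, a ratio of 21.8 with a counting interval of 5.67 to 186. Imprinted genes rose in 21 of 42 and fell in 10 (23 and 11 adjusted over the list alone, camera adjusted p = 0.114), with IGF2R, the mannose-6-phosphate receptor, at 0.86 log2. HOX genes rose in 6 of 16 and fell in 3 by either adjustment (camera adjusted p = 0.319), HOXB6 by 3.05 and HOXA9 by -0.69 log2. Olfactory receptors rose in 11 of 34 and fell in 1 (11 and 0 adjusted over the list alone, camera adjusted p = 0.0802, but 0.0242 without DMSO replicate 1). ZNF zinc finger genes, mostly transcriptional repressors, rose in 60 of 502 and fell in 176 (57 and 167 adjusted over the list alone). Their camera adjusted p of 0.0451 became 0.0632 with a replicate term, 0.08 under a filter of 1 CPM and 0.303 with an estimated correlation. The ZNF call also ended without DMSO replicate 2.

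Genes of the methylation enzymes went both ways with decitabine. DNMT3B, a de novo DNA methyltransferase, fell from 101 ± 4.06 to 54.9 ± 0.609 CPM (SD, n = 2) and DNMT3A rose by 0.37 log2. UHRF1, which guides DNMT1 to replicated DNA, fell by 0.35 log2, EHMT1 by 0.23 and EHMT2 by 0.19. DNMT1, the maintenance methyltransferase, was at -0.11 log2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0242), a call that ended without DMSO replicate 1 (adjusted p 0.0938), DMSO replicate 2 (0.0619) or DAC replicate 2 (0.181). It also ended with upper quartile factors (adjusted p 0.198), library size only (0.133) and a filter of 1 CPM (0.148). Of 18 DNA methylation genes, 8 rose and 8 fell by either adjustment (camera adjusted p = 0.565), and of 33 H3K9 methylation genes 6 rose and 13 fell by either adjustment (camera adjusted p = 0.0941), SETDB2 by -1.40 log2. SAMHD1, which breaks down deoxynucleotide triphosphates and the active form of decitabine, fell from 197 ± 3.89 to 38.9 ± 2.41 CPM. Nucleoside drug metabolism genes rose in 4 of 17 and fell in 10 by either adjustment (camera adjusted p = 0.00521, adjusted p = 0.303 with an estimated correlation).

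The remaining decitabine lists were T and NK cells (11 of 20 higher and 3 lower by either adjustment, perforin PRF1 2.47 log2, camera adjusted p = 0.0121, adjusted p = 0.228 with an estimated correlation) and endothelial and stromal cells (10 of 17 higher and 2 lower by either adjustment, LUM, lumican, 3.39 log2, camera adjusted p = 0.018, adjusted p = 0.269 with an estimated correlation). Lists that camera did not call were lysosome (23 of 51 higher, 12 lower, and 23 and 13 adjusted over the list alone, camera adjusted p = 0.106), sterol synthesis (7 of 31 higher, 12 lower by either adjustment, 0.564), integrated stress response (12 of 39 higher, 13 lower by either adjustment, but 13 and 12 under library size only and 13 and 11 with upper quartile factors, 0.987) and abundant non-coding RNA (3 of 6 higher, 1 lower by either adjustment, 0.227). Sterol synthesis had a median of -0.05 and a mean of 0.02 log2. By fry, which tests a list by itself, 8 lists not called by camera passed with decitabine, by adjusted p: cancer-testis and germline (0.00157), H3K9 methylation (0.00161), imprinted (0.00304), lysosome (0.00395), DNA methylation (0.012), HOX clusters (0.0121), abundant non-coding RNA (0.0165) and olfactory receptors (0.0205). Fry called 19 lists higher and 12 lower of the 35, and 56.2% of all tested genes were called with decitabine. Passing fry therefore does not set these lists apart from other genes.

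In total, 5072 of 18452 genes were higher and 5306 lower with decitabine by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 1889 were higher and 567 lower by at least 2-fold. Without an adjustment, 11227 genes had a p under 0.05. Long non-coding genes were called higher about as often as protein-coding genes (29% against 27.9%, Fisher's exact test, two-sided, odds ratio 1.06, adjusted p = 0.266) and lower less often (9.3% against 33.2%, odds ratio 0.207, adjusted p = 1e-131). Among calls of at least 2-fold this difference ended (3% against 3.1%, odds ratio 0.961, adjusted p = 0.89, same exact test). These exact tests take genes as independent units, which they are not, so their p-values do not measure the spread between libraries. Pseudogenes gave odds ratios of 1.12 for higher (adjusted p = 0.211) and 0.245 for lower calls (adjusted p = 4.49e-39), and small or other genes 0.441 (adjusted p = 3.81e-18) and 0.266 (adjusted p = 7.41e-43), by the same exact test. At a mean of at least 1 CPM, the odds ratios for higher calls were 1.43 for long non-coding genes and 1.5 for pseudogenes (adjusted p = 2.73e-07 and 0.000148, same exact test). For lower calls at 1 CPM they were 0.253 for long non-coding genes, 0.301 for pseudogenes and 0.748 for small or other genes (adjusted p = 5.28e-66, 3.18e-22 and 0.0426, same exact test). Among calls of at least 2-fold, long non-coding genes gave 1.53 for higher calls (adjusted p = 1.28e-08, same exact test), and small or other genes 1.07 for higher and 1.38 for lower calls, on the other side of 1 (adjusted p = 0.654 and 0.108, same exact test).

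**Figure D2:**
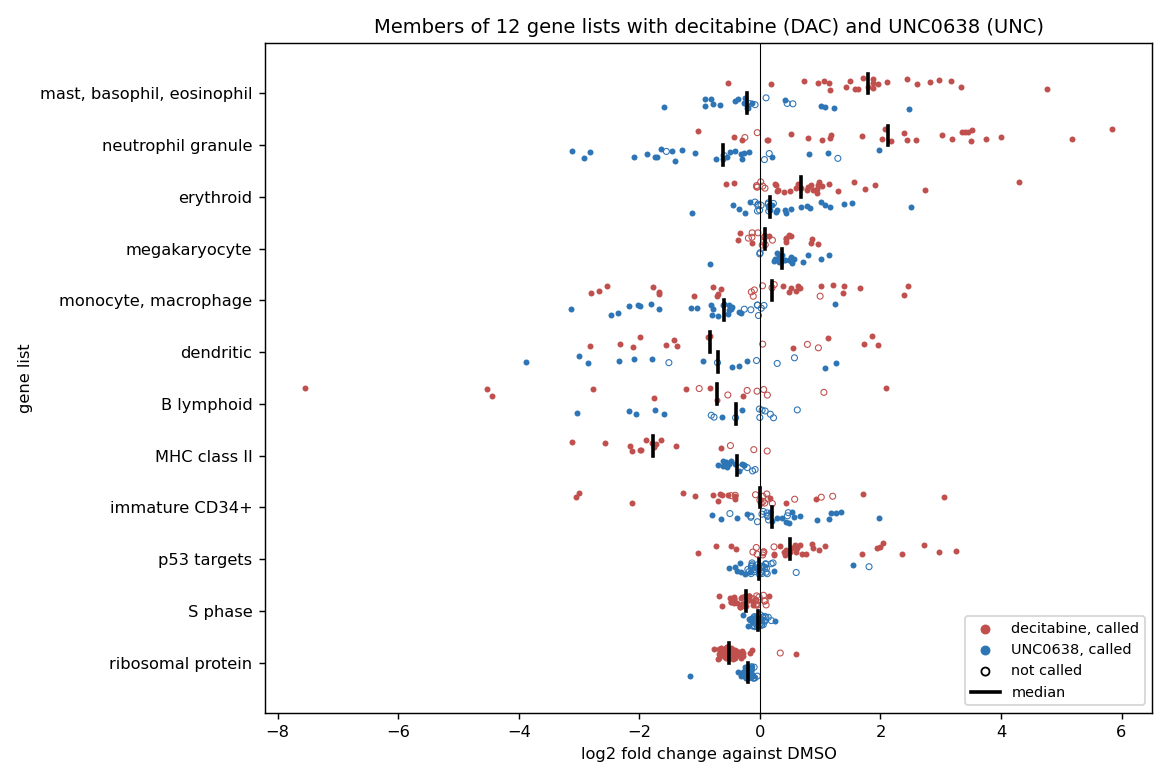
Log2 fold change against DMSO of each member of 12 gene lists, decitabine in red and UNC0638 in blue. Filled points passed the test, open points did not, and black bars are medians. The mast cell, basophil and eosinophil median was 1.79 with decitabine and -0.22 with UNC0638, and the neutrophil granule median 2.12 and -0.61.

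The next comparison asked which transcripts differed after inhibition of G9a and GLP. Fetal globin genes rose. HBG2 went from 81.0 ± 12.7 to 479.6 ± 33.4 CPM and HBG1 from 55.1 ± 14.3 to 326 ± 21.9 CPM (SD, n = 2), while HBD fell from 171 ± 14.3 to 78.3 ± 1.10 CPM and HBB by 0.45 log2. HBG2 made up 74.2% ± 0.42 of HBG2 plus HBB counts (SD, n = 2), against 26.1% ± 2.33 in DMSO (t test with pooled variance, Benjamini-Hochberg adjusted p = 0.000385). HBE1 rose by 0.97 log2 and BCL11A was at -0.03 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.727). Of 10 globin genes, 3 rose and 3 fell (5 and 3 adjusted over the list alone, under library size only or with upper quartile factors), HBZ, embryonic zeta globin, being the other that fell (-1.77 log2, but -1.40 with an edgeR adjusted p of 0.0643 without UNC replicate 2). The list's median was -0.09, its mean 0.09, and camera placed it higher (adjusted p = 0.00734, 0.0743 with a replicate term and 0.224 with an estimated correlation). Of 33 erythroid genes, 17 rose and 5 fell (19 and 5 adjusted over the list alone, camera adjusted p = 6.78e-08, adjusted p = 0.118 with an estimated correlation). RHAG, the Rh-associated glycoprotein of red cells, went from 56.3 ± 1.52 to 148 ± 0.228 CPM.

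Neutrophil and monocyte genes fell with UNC0638. ELANE, neutrophil elastase, went from 439.5 ± 14.8 to 141 ± 4.84 CPM (SD, n = 2), PRTN3, proteinase 3, from 228 ± 2.97 to 53.6 ± 4.22 CPM, and LYZ from 903 ± 30.9 to 275 ± 21.0 CPM. MPO fell by 0.54 log2. Of 30 neutrophil granule genes, 21 fell and 4 rose (21 and 5 adjusted over the list alone, camera adjusted p = 2.53e-33, adjusted p = 0.0622 with an estimated correlation). The risers were the secondary granule genes LTF (1.98 log2) and LCN2 (0.81), RNASE3 (1.12) and CTSG (0.20). By edgeR, the LTF call ended without DMSO replicate 2 (1.48 log2, adjusted p 0.11) or UNC replicate 2 (1.38, adjusted p 0.142), and the CTSG call without DMSO replicate 1 (0.14, adjusted p 0.117) or with counts summed over transcripts (0.16, adjusted p 0.0554). Of 31 monocyte and macrophage genes, 23 fell and 1 rose (24 and 1 adjusted over the list alone, camera adjusted p = 4.12e-23, adjusted p = 0.0907 with an estimated correlation). MRC1 went from 142 ± 2.88 to 25.7 ± 1.69 CPM, the proteoglycan gene VCAN fell by 2.02 log2, and the riser was the apolipoprotein gene APOE (1.49 ± 0.00940 to 3.55 ± 0.245 CPM).

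Dendritic cell genes fell in 10 of 17 cases and rose in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.000437, adjusted p = 0.118 with an estimated correlation). The lectin gene CLEC10A fell by 2.35 log2 and the transcription factor gene IRF4 went from 4.37 ± 0.228 to 0.548 ± 0.104 CPM (SD, n = 2), while FCER1A rose by 1.09 and CLEC9A, a receptor for dead cells, by 1.27. The CLEC9A call ended by edgeR without DMSO replicate 1 (adjusted p 0.176) or UNC replicate 1 (0.152), with DESeq2's Wald test (0.0642) and with counts summed over transcripts (0.0757). MHC class II genes fell in 12 of 16 cases and none rose (13 and 0 adjusted over the list alone, CD74 -0.61 log2, camera adjusted p = 7.7e-10, adjusted p = 0.111 with an estimated correlation). MHC class I genes fell in 8 of 16 by either adjustment, and in 5 under library size only (camera adjusted p = 0.00266, adjusted p = 0.13 with an estimated correlation). B lymphoid genes fell in 7 of 17 by either adjustment, DNTT by 1.74 log2 (camera adjusted p = 0.000437, adjusted p = 0.193 with an estimated correlation). In the T and NK list 6 of 20 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.00257, adjusted p = 0.13 with an estimated correlation), with the T cell surface genes CD2 and CD3E at 3.64 and 3.01 log2. Of 25 mast cell, basophil and eosinophil genes, 15 fell and 5 rose by either adjustment (camera adjusted p = 0.00257, adjusted p = 0.13 with an estimated correlation). PRG2 and CLC fell by 0.77 and 0.81 log2, whereas the IgE receptor genes MS4A2 and FCER1A, the mast cell chymase gene CMA1 (2.48), ALOX15 (1.01) and PRG3 (0.42) rose.

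Megakaryocyte and immature cell genes rose with UNC0638. VWF, von Willebrand factor, went from 98.6 ± 4.28 to 199 ± 14.8 CPM (SD, n = 2) and ITGA2B from 698 ± 29.8 to 1002 ± 19.9 CPM. Of 22 megakaryocyte genes, 19 rose and 1 fell (PDGFA, -0.82 log2) by either adjustment (camera adjusted p = 2.75e-16, adjusted p = 0.193 with an estimated correlation). MEIS1, a stem cell homeobox factor, rose by 0.56 log2. Of 31 immature cell genes, 15 rose and 4 fell (16 and 4 adjusted over the list alone, camera adjusted p = 6.43e-05, adjusted p = 0.118 with an estimated correlation). Those that fell were FLT3 (-0.65), HOPX (-0.80), SPINK2 (-0.38) and KIT (-0.22). The SPINK2 call ended by edgeR without DMSO replicate 2 (-0.25, adjusted p 0.264), UNC replicate 1 (-0.38, 0.0783) or UNC replicate 2 (-0.39, 0.0656) and under library size only (-0.30, 0.0725). CD34 was at 73.3 ± 1.01 CPM in DMSO and 80.9 ± 1.61 CPM in UNC0638 (SD, n = 2), with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0572. CD34 passed with upper quartile factors (adjusted p 0.034), library size only (0.0058), limma-voom (0.0415), the groups compared alone (0.0315), a replicate term (0.0296), a filter of 1 CPM (0.0268), and without DAC replicate 1 (0.0468) or DAC replicate 2 (0.0466).

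ZNF zinc finger genes fell with UNC0638. ZNF841 went from 17.0 ± 0.528 to 5.55 ± 0.0106 CPM (SD, n = 2). ZNF274, which directs an H3K9 methyltransferase to zinc finger gene clusters, went from 18.4 ± 0.272 to 6.24 ± 0.634 CPM, and ZNF667, overlapped by its antisense RNA ZNF667-AS1, from 6.53 ± 0.804 to 0.697 ± 0.0414 CPM. Of 502 tested members, 219 fell and 30 rose (229 and 37 adjusted over the list alone, camera adjusted p = 4.46e-13, adjusted p = 0.0907 with an estimated correlation). The split followed the chromosome: of 247 members on chromosome 19, 163 fell and 1 rose, with a median of -0.54 log2, while of 255 members elsewhere 56 fell and 29 rose, with a median of -0.03. Under library size only, the scaling with the largest change, 192 members fell and 48 rose. With decitabine the medians of both sets were near each other, -0.15 on chromosome 19 and -0.14 elsewhere.

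**Figure D3:**
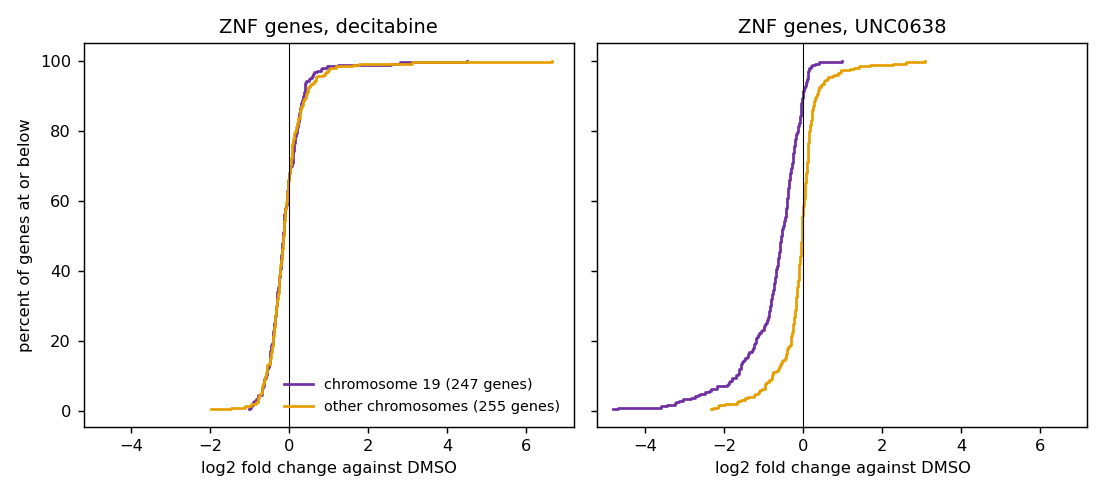
Cumulative percent of ZNF genes by log2 fold change against DMSO, for 247 genes on chromosome 19 and 255 on other chromosomes, with decitabine and with UNC0638. With UNC0638 the medians were -0.54 on chromosome 19 and -0.03 elsewhere.

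Among single genes, the long non-coding RNA LINC02154 had 638 counts with UNC0638 against 2 in DMSO, a ratio of 379 with a 95% counting interval of 104 to 3140. LINC01088, another long non-coding RNA, went from 0.108 ± 0.0184 to 5.20 ± 0.182 CPM (SD, n = 2). UGT1A6 and 7 other UGT1A glucuronosyltransferase entries, which share their last exons and so their reads, rose by 5.10 to 5.89 log2 from 5 to 7 counts in DMSO. With decitabine UGT1A6 rose by 5.71 log2.

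Immediate early genes fell in 17 of 23 cases and rose in 1 by either adjustment, FOS by 1.10 and JUN by 1.28 log2 (camera adjusted p = 1.63e-11, adjusted p = 0.163 with an estimated correlation). Lysosome genes fell in 34 of 51 and none rose (36 and 0 adjusted over the list alone), with the protease gene CTSH at -1.05 log2 (camera adjusted p = 2.81e-11, adjusted p = 0.111 with an estimated correlation). Ribosomal protein genes fell in 70 of 78 and none rose (75 and 0 adjusted over the list alone), by a median of 0.19 log2, with 45 lower under library size only (camera adjusted p = 4.46e-13, adjusted p = 0.41 with an estimated correlation). Replication histones fell in 44 of 66 and rose in 2 (48 and 2 adjusted over the list alone, 25 lower and 2 higher under library size only, H3C3 -0.33 log2, camera adjusted p = 1.23e-07, adjusted p = 0.459 with an estimated correlation). Integrated stress response genes fell in 14 of 39 and none rose (16 and 0 adjusted over the list alone, 9 lower under library size only), with the serine synthesis gene PSAT1 at -0.98 log2 (camera adjusted p = 0.000224, adjusted p = 0.193 with an estimated correlation).

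DNMT3A rose by 0.30 log2 and UHRF1 fell by 0.23. DNMT3B was at 0.22 log2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00227), which became 0.13 without DMSO replicate 1 (adjusted p 0.161). DNMT1 was at -0.12 log2 (adjusted p = 0.0289 by the same edgeR test), a call that ended without DMSO replicate 2 (0.0914) or UNC replicate 2 (0.0998), with upper quartile factors (0.0634), library size only (0.461) and a filter of 1 CPM (0.0538). The targets of the inhibitor, EHMT1 at 0.05 and EHMT2 at -0.07 log2, did not pass by that edgeR test (adjusted p = 0.515 and 0.26). SAMHD1 fell by 1.14 log2. The imprinted antisense RNA KCNQ1OT1 rose by 0.67 log2 and the gene it overlaps on the other strand, KCNQ1, fell by 1.41.

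Lists that camera did not call with UNC0638, by camera adjusted p, were olfactory receptors (3 of 34 higher, none lower, and 2 and 0 adjusted over the list alone, 0.0541), protocadherins (1 of 22 lower, 0 adjusted over the list alone, 0.0784), HOX clusters (5 of 16 higher and 1 lower by either adjustment, 0.121), interferon response (11 of 42 higher and 5 lower, 13 and 8 adjusted over the list alone, 0.353) and nucleoside drug metabolism (3 of 17 each way, 4 and 3 adjusted over the list alone, 0.431). The olfactory receptor list passed without DMSO replicate 1 (0.00176), DAC replicate 2 (0.0376) or UNC replicate 2 (0.0161) and with DESeq2 size factors (0.0347). Protocadherins passed without DMSO replicate 2 (3.74e-05) or UNC replicate 1 (0.0073), and HOX clusters without DMSO replicate 1 (0.0473). With a replicate term, olfactory receptors (camera adjusted p 0.03) and protocadherins (0.0261) passed. Abundant non-coding RNA (2 of 6 each way), keratins (3 of 15 higher, 1 lower), H3K9 methylation (2 of 33 higher, 4 lower) and S phase (1 of 44 higher, 5 lower, and 0 and 1 adjusted over the list alone) all gave 0.523, the first 3 with equal counts adjusted over the list alone.

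The others were imprinted genes (8 of 42 higher, 12 lower, and 9 and 14 adjusted over the list alone, 0.59), endothelial and stromal (3 of 17 each way, 3 and 4 adjusted over the list alone, 0.605), DNA methylation (5 of 18 higher, 4 lower by either adjustment, 0.63) and mitosis (2 of 37 higher, 6 lower, and 2 and 5 adjusted over the list alone, 0.651), all camera adjusted p. Sterol synthesis (5 of 31 higher, 3 lower, and 4 and 3 adjusted over the list alone, 0.655), p53 targets (2 of 39 higher, 7 lower, and 2 and 4 adjusted over the list alone, 0.719), cancer-testis and germline (1 of 20 each way by either adjustment, 0.828) and inflammatory genes (8 of 34 higher, 11 lower, and 8 and 12 adjusted over the list alone, 0.908) completed them. Under library size only, the balance of calls turned around in 5 lists: mitosis (8 higher, 1 lower), S phase (5 and 1), p53 targets (5 and 2), H3K9 methylation (6 and 4) and imprinted genes (11 and 9). With DESeq2 size factors it turned around for sterol synthesis (3 and 4). By fry, which called 6 lists higher and 14 lower with UNC0638, HOX clusters (adjusted p 0.0281) and H3K9 methylation (0.0314) passed. Median, mean and camera's direction differed in sign in 7 of the 35 UNC0638 lists, of which globins alone passed. CCL5 and TNF, inflammatory cytokines, rose by 1.24 and 1.61 log2.

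In total, 2423 genes were higher and 2898 lower with UNC0638 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 731 were higher and 392 lower by at least 2-fold, and 7159 had an unadjusted p under 0.05. Under library size only the split was 3535 higher and 1862 lower, while the median log2 fold change of all genes moved to 0.08. The count of genes higher was 1592 without DMSO replicate 1, 1492 without DMSO replicate 2 and 1596 without UNC replicate 1. Long non-coding genes and pseudogenes were called higher more often than protein-coding genes (17.9% and 23.4% against 12.3%, Fisher's exact test, two-sided, odds ratios 1.56 and 2.17, adjusted p = 6.64e-12 and 2.81e-14). For lower calls the odds ratios were 0.187 and 0.194 (adjusted p = 8.34e-80 and 6e-27, same exact test). Small or other genes gave 0.554 for higher and 0.159 for lower calls (adjusted p = 6.8e-06 and 1.61e-36, same exact test), and 1.01 for higher calls among genes of at least 1 CPM (adjusted p = 0.921, same exact test). Among calls of at least 2-fold, lower calls gave 0.564 for long non-coding genes, 0.708 for pseudogenes and 0.369 for small or other genes (adjusted p = 0.00752, 0.422 and 0.0103, same exact test).

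The direct comparison of UNC0638 with decitabine tested whether genes responded differently to the inhibitors. Granule genes were lower with UNC0638 than with decitabine: PRG2 was 7653 ± 83.6 CPM with decitabine and 1037 ± 29.6 CPM with UNC0638 (SD, n = 2), and BPI was 149 ± 0.592 CPM and 1.57 ± 0.256 CPM. With UNC0638 against decitabine, the defensin gene DEFA3, which has near-identical copies, fell by 8.96 log2 and APOC2 by 8.68, while DNTT rose by 5.80 and GPA33, a cell surface antigen, by 4.53. HBG2 was 0.84 log2 higher and HBE1 lower at -4.26 log2. CD34 (1.22 log2) and HLA-DRA (1.52) were higher with UNC0638, and ZNF274 (-1.86) lower. Of 30 neutrophil granule genes 26 were lower and 2 higher (camera adjusted p = 1.99e-71, adjusted p = 0.0118 with an estimated correlation). Of 25 mast cell, basophil and eosinophil genes 23 were lower and 2 higher (camera adjusted p = 4.42e-68, adjusted p = 0.0118 with an estimated correlation). Of 16 MHC class II genes 13 were higher and 1 lower (camera adjusted p = 1.38e-19, adjusted p = 0.0484 with an estimated correlation), and each of these 3 lists had the same counts adjusted over the list alone. Immediate early genes, which also respond to handling, were lower in 21 of 23 cases and higher in 1 by either adjustment (camera adjusted p = 2.98e-09, adjusted p = 0.273 with an estimated correlation). Immature cell genes were higher in 21 of 31 cases and lower in 4 (21 and 5 adjusted over the list alone, camera adjusted p = 2.39e-07, adjusted p = 0.0764 with an estimated correlation). On chromosome 19, 142 of 247 ZNF genes were lower and 17 higher, and over all 502 members 190 were lower and 103 higher (191 and 103 adjusted over the list alone, camera adjusted p = 0.0836, fry adjusted p = 0.00244).

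In this direct comparison 5608 genes were higher and 4858 lower with UNC0638 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 894 were higher and 1759 lower by at least 2-fold, and 11248 had an unadjusted p under 0.05. Long non-coding genes gave odds ratios of 0.42 for higher and 0.528 for lower calls against protein-coding genes (Fisher's exact test, two-sided, adjusted p = 1.74e-53 and 5.62e-29), pseudogenes 0.548 and 0.483 (adjusted p = 7.43e-11 and 3.61e-13, same exact test) and small or other genes 0.37 and 0.23 (adjusted p = 3.08e-28 and 3.87e-43, same exact test). Among higher calls of at least 2-fold the odds ratios were above 1, at 1.51, 1.34 and 1.55 (adjusted p = 0.000132, 0.109 and 0.0103, same exact test). Among lower calls of at least 2-fold, long non-coding genes gave 0.86 and pseudogenes 0.719 (adjusted p = 0.106 and 0.0503, same exact test). At a mean of at least 1 CPM, small or other genes gave 0.963 for higher and 0.339 for lower calls (adjusted p = 0.89 and 1.57e-09, same exact test).

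Both treatments raised 1167 genes, the fetal globins HBG1 and HBG2 and the megakaryocyte genes VWF and ITGA2B among them, against 666 for independent lists. Both lowered 1075, among them CD74, SAMHD1 and MRC1, against 833.3 for independent lists. A further 1008 rose with decitabine and fell with UNC0638, such as PRG2 and ELANE, against 796.6 for independent lists, and 394 did the reverse, such as PROM1, against 696.8. The value for independent lists takes every gene as equally easy to call, so an excess over it does not by itself show a shared response. Because both contrasts use the same DMSO libraries, unchanged groups with shared controls were simulated: over 20 simulations the mean shared calls were 0.15 higher and 0.05 lower. With no change simulated few genes are called at all, so these counts cannot show how shared controls affect overlap among real calls. The correlation of log2 fold changes across genes, which are not independent replicates, was r = 0.337 and the covariance 0.225, against 0.491 and 0.028 in the simulations. The simulated r comes from the shared controls alone and is no baseline for the observed r. Without DMSO replicate 2 the shared calls were 692 higher and 647 lower, and under library size only those lower were 609. With DMSO replicate 1 as the control of decitabine alone and DMSO replicate 2 as that of UNC0638 alone, shared calls were 769 higher and 749 lower, against 402.7 and 525.7 for independent lists, and r was 0.249. With the DMSO libraries exchanged they were 662 higher and 625 lower, against 360.1 and 502, and r was 0.226. Calls in opposite directions were then 721 and 714 for higher with decitabine and lower with UNC0638, against 482.4 and 476.2, and 222 and 250 for the reverse, against 438.9 and 379.5.

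By camera, 13 lists were higher and 10 lower with decitabine, 5 and 13 with UNC0638, and 7 and 12 with UNC0638 against decitabine. With an estimated correlation these were 2 and 1, none, and 1 and 2: the mast cell, basophil and eosinophil, neutrophil granule and MHC class II lists, in both comparisons with decitabine. A call that ended this way does not by itself show correlated members. With UNC0638 against DMSO, calls also ended for lists with estimates below the preset 0.01. These included mast cell, basophil and eosinophil (-0.008), T and NK (-0.039) and MHC class I genes (-0.015).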

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

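The test behind the counts in this part was chosen only after the data were seen. Of 315 tested transcript entries with no gene name, which no comparison above used, 28 were at least 2-fold higher with decitabine than in DMSO and past the edgeR test. With UNC0638, 15 of the same 315 entries were at least 2-fold higher. In all, 93 of these entries were higher and 37 lower with decitabine, and 85 higher and 20 lower with UNC0638.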

How the results depend on the processing

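Alternatives chosen only after the data were seen were library size only, counts summed over transcripts, every transcript entry by itself, 1 DMSO library for each contrast, and the fit without genes that match an overlapping neighbour. The counts of genes higher and lower in each comparison and in both stayed within 1.5 times of their values with DESeq2 size factors, upper quartile factors, DESeq2's Wald test, limma-voom, other filters, only the groups compared, summed transcripts and the fit without the genes above. Where no cause is named for a change below, the cause was not tested. Most named genes were picked from these same data for large changes or small adjusted p. Their stability therefore does not stand for that of other genes. No named gene reversed: across other scalings, filters, tests and features 1 of 168 decitabine calls, 19 of 169 UNC0638 calls and 0 of 17 calls of UNC0638 against decitabine ended somewhere, and 2, 29 and 0 when 1 library was left out.

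At 2-fold or more, a stricter rule by construction, genes higher and lower were 1889 and 567 with decitabine, 731 and 392 with UNC0638, 894 and 1759 for UNC0638 against decitabine, and 304 and 75 shared. At an adjusted p under 0.01, UNC0638 had 1424 higher and shared calls were 662 higher and 645 lower. With every transcript entry tested, which counts 1 gene several times, they were 14711 and 15059, 6920 and 8316, and 16064 and 14469. Under library size only, UNC0638 had 1862 lower and 609 shared lower.

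Leaving out each library in turn, where a lone library was assumed to vary like the other groups, gave 4057 to 5207 higher and 4518 to 5474 lower with decitabine, 1492 to 2206 and 2033 to 2953 with UNC0638, and 4728 to 5593 and 4041 to 5267 between them. Shared calls were 692 to 1129 higher and 647 to 1177 lower, lowest without DMSO replicate 2. With 1 DMSO library for each contrast they were 769 higher and 749 lower, or 662 and 625 with these exchanged. Lists called were 12 to 14 higher and 9 to 10 lower with decitabine, 5 to 7 and 13 to 14 with UNC0638, and 6 to 7 and 11 to 12 between them.

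With an estimated correlation, list calls were 2 higher and 1 lower with decitabine, 0 and 0 with UNC0638, and 1 and 2 between them. Calls also ended for lists whose estimate lay below the preset 0.01, so these losses do not measure correlation alone. By fry, which does not compare a list with other genes, there were 11 and 20 between them.

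For gene classes at 2-fold or more, odds ratios with decitabine were 1.53 for higher and 0.961 for lower long non-coding genes and 1.07 and 1.38 for small or other genes. With UNC0638 they were 0.971 for higher small or other genes, and 0.564, 0.708 and 0.369 for lower long non-coding, pseudogene and small or other genes. Between treatments they were 1.51, 1.34 and 1.55 for higher long non-coding, pseudogene and small or other genes, and 0.86 and 0.719 for lower long non-coding genes and pseudogenes. At a mean of 1 CPM or more, they were 1.43 and 1.5 for long non-coding genes and pseudogenes higher with decitabine. For small or other genes they were 1.01 for calls higher with UNC0638 than in DMSO, and 0.963 for calls higher with UNC0638 than with decitabine.

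Deviations of libraries with equal replicate numbers correlated at 0.036, 0.044 and 0.005 across all tested genes. Genes of low count were included, so this does not exclude pairing. The third principal component (6.5% of variance) was positive in each replicate 1 and negative in each replicate 2, weakly in DAC (0.95 and -2.73). With a replicate term, decitabine had 5221 higher and 5512 lower, UNC0638 2644 and 3244, and the direct comparison 5796 and 5043. Each count was above that without the term. That term ended the ZNF call with decitabine (adjusted p 0.0632) and the globin call with UNC0638 (0.0743), and gave calls to olfactory receptors (0.03) and protocadherins (0.0261) with UNC0638 and to CD34 (0.0296). In simulated data 60% of 2-fold changes and 98% of 4-fold changes were called, so small changes can be missed at this depth and number of libraries.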

Other observations

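Tests chosen only after the result was seen were those of scaling and of a fixed eosinophil cell type for granule genes, the test of chromosome 19 as a whole, the counts of genes detected in 1 group and the counts of opposite isoforms. TERC, the RNA template of telomerase, moved in opposite directions: it was 15.4 ± 0.757 CPM in DMSO, 34.4 ± 2.47 CPM with decitabine and 6.25 ± 0.892 CPM with UNC0638 (SD, n = 2). NEAT1, the long non-coding RNA that scaffolds paraspeckles, rose with both, by 0.95 log2 with decitabine and 0.78 with UNC0638. The extracellular matrix gene LUM rose by 3.39 log2 with decitabine and fell by 1.27 with UNC0638. MEST, an imprinted gene expressed from the paternal copy, rose by 1.09 log2 with UNC0638. The interferon-induced antiviral gene OAS3 rose by 0.77 log2 and IL1B, a cytokine of inflammation, by 0.67 with UNC0638.

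Among the 45 genes counted at least 10 times in each DAC library and never in DMSO were PRAME, a cancer-testis gene, RTL1, an imprinted retrotransposon-derived gene, DCN, the matrix proteoglycan decorin, and RELN, reelin, all named after their values were seen. With UNC0638 there were 3 such genes, MIR9-1HG, OR2D2 and PCA3, also named after their values were seen. OR2D2, an olfactory receptor, had 21 counts against none in DMSO, at least 8.32-fold higher against 3 counts over the group. Its edgeR call ended without DMSO replicate 2 (adjusted p 0.0509). With decitabine, 3 of 9986 genes with several tested entries had transcripts called in opposite directions by at least 1.5-fold each: ERG, LINC-PINT and OPRM1, again named after their values were seen. In each, 1 direction rested on entries of low mean abundance: 0.733 CPM for ERG, 0.11 for OPRM1, and 0.915 and 0.628 for LINC-PINT.

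ZNF genes fell with UNC0638 as a list, by a median of 0.216 log2 over 502 members (camera adjusted p = 4.46e-13, but adjusted p = 0.0907 with an estimated correlation). Low expression is argued against, since none of 10000 random lists matched on mean CPM had a median as low (percentile 0), and GC content and transcript length likewise (percentile 0 of 10000 matched lists). These tests cover the whole list, and the difference between chromosome 19 and other chromosomes was not matched on them. A fall of chromosome 19 genes as a whole is argued against as the only cause by a median of ZNF genes there 0.44 log2 below that of the 1057 other genes of the chromosome (difference -0.44). A part shared by the chromosome stays open: the median of those other genes was -0.098 log2, with 300 lower and 57 higher (28.4% lower, against 14.1% of the remaining genes outside the list). Against decitabine 463 of them were lower and 148 higher. That comparison includes a rise with decitabine: against DMSO, 371 of them were higher and 196 lower with decitabine, with a median of 0.128 log2. ZNF genes on chromosome 19 had a median 0.504 log2 below ZNF genes elsewhere (permutation p 1e-05, two-sided, the smallest that 100000 resamples can give). That permutation shuffles genes, which are not independent, so its p does not measure the spread between libraries. Which genes lie in clusters was not determined, so an effect of the chromosome 19 clusters cannot be told apart from other features of these genes. Whether H3K9me2 was lost at ZNF genes was not measured. The mark is tied to silent genes, so its loss alone would be expected to raise them. On chromosome 19, 163 of 247 members fell and 1 rose. This argues against loss of the mark alone as a direct cause of the fall there, but does not show whether the mark was lost. An indirect effect was not tested. Measuring the mark at ZNF genes on chromosome 19 and elsewhere, with and without UNC0638, would show whether it was lost.

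Granule genes rose with decitabine. Scaling between libraries is argued against, since a library factor moves every gene alike: the median of the mast cell, basophil and eosinophil list lay 1.78 log2 above that of the 18427 other genes (0.013, quartiles -0.28 and 0.46). More cells of 1 fixed eosinophil type stay open. The changes of PRG2, PRG3, EPX, CLC, RNASE2 and RNASE3 ran from 1.63 to 2.98 log2, an SD 13.49 times the median standard error. Equal factors would be expected only if 1 cell type supplied all 6 transcripts, which was not measured. A shift in which cells were present and a change within cells cannot be told apart in bulk RNA.

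The 22 tested protocadherins, all of the gamma cluster, rose together with decitabine. Reads of shared exons are a candidate explanation for their common movement, since a median of 92.8% of a member's count was also counted for every other member. The counts above that shared part were higher in both DAC libraries than in both DMSO libraries for 15 of 22 members, which share reads and so are not independent trials. Shared reads therefore leave open whether single members rose.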
